A study of Homo sapiens with 12 samples.

How the data were processed

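The labels describe messenger RNA sequencing of THP-1 cells, a human monocytic leukaemia line, in 12 samples. Per the labels' protocols, total RNA was extracted with a commercial kit and made into strand-specific mRNA libraries. Per the submitters' processing notes, the genome build was GRCh38.p13. The aligner, the counting tool and the gene annotation are not given in the sources used here. Many gene symbols of the table differ from those of GENCODE release 29, an annotation of GRCh38, so it is unclear which annotation and build the counting used.

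The deposited table is a gene count matrix by its title, with 12 value columns, each named by flow cell, run, library and lane. None of these names occurs in the title, description, source name, characteristics or protocol of any sample. All 12 value columns were therefore matched to no sample and no group. The order of the columns and the counts themselves were not used to assign them, and the counts were not analysed here. Sequencing run records and other parts of the submitted workbook were not searched for a key from run names to samples. No library total, expression level, fold change or test is reported for this reason.

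The results use only the header and the gene symbol and gene ID of each row, read with Python 3.11.15. Column names were compared with the labels after removing case and punctuation, both whole and in pieces of at least 4 characters. Gene IDs were looked up in GENCODE release 29 on GRCh38, and coordinates are from that annotation. Before the data were examined, 27 gene lists, the 4 groups, the tests and the rule for the genes to be named were fixed. The genes located in the results are those that the rule names in every comparison, and no gene was chosen by its values. The planned edgeR quasi-likelihood tests were not run.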

Results

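The series concerns THP-1 cells, an undifferentiated human monocytic line grown submerged, and asks how crosstalk with a second cell type bears on cytochrome expression in a model of the alveolar barrier. Its labels put 12 samples in 4 groups of 3. THP-1 cells were cultured alone or together with A549, a human lung adenocarcinoma line with alveolar epithelial features. In each culture they were either exposed to BaP or kept as what the design text calls a negative control. The exposure was taken as 48 h, a time that the sample titles give only for the cells cultured alone. The dose is not stated in the labels. The titles of the coculture samples write the partner line as A459, and the design text as A549. The design implies the effect of BaP in each culture, the effect of coculture with and without BaP, and the difference between the BaP responses of both cultures.

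None of these comparisons was made here. The 12 value columns of the count table carry sequencing run names that match no sample label, so no library was placed in a group. Sources beyond the labels and this table, such as sequencing run records, were not searched for a key. Whether any gene rose or fell with BaP or with coculture was not tested, and library depths per group are not given.

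The table listed 57773 genes, each with a different Ensembl gene ID. Of these IDs, 52338 (90.6%) were found in GENCODE release 29, and 5435 were not. Among the rows found, 29783 carried the same symbol as that release. The annotation behind the counts is therefore unclear, although the submitters name GRCh38.p13 as the build, and the coordinates given here are those of GENCODE release 29 alone. The matched rows held 19263 protein-coding genes, 9749 processed pseudogenes, 6576 long intergenic non-coding RNA genes and 5097 antisense genes.

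Having a row in the table says nothing about the expression of a gene. All 57 genes of the cytochrome P450 list had a row, as did all 23 genes of the aryl hydrocarbon receptor target list and all 52 genes of the list of other xenobiotic metabolism genes. The cytochrome P450 list includes CYP1A1, CYP1A2 and CYP1B1, enzymes that oxidise polycyclic aromatic hydrocarbons. In GENCODE release 29 coordinates on GRCh38, the protein-coding gene CYP1A1 (ENSG00000140465) lies on the minus strand of chromosome 15 from 74719542 to 74725610. Its paralog CYP1A2 (ENSG00000140505) lies on the plus strand of the same chromosome from 74748844 to 74756202. CYP1B1 (ENSG00000138061) lies on the minus strand of chromosome 2 from 38066973 to 38109902. AHR (ENSG00000106546), the receptor that binds these hydrocarbons, lies on the plus strand of chromosome 7 from 16916359 to 17346152. AHRR (ENSG00000063438), which encodes its repressor, lies on the plus strand of chromosome 5 from 304176 to 438291.

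TIPARP (ENSG00000163659), a receptor target that encodes a mono-ADP-ribosyltransferase, lies on the plus strand of chromosome 3 from 156673235 to 156706770. NQO1 (ENSG00000181019), a quinone reductase gene, lies on the minus strand of chromosome 16 from 69706996 to 69726951. ALDH3A1 (ENSG00000108602), an aldehyde dehydrogenase gene, lies on the minus strand of chromosome 17 from 19737984 to 19748943. No expression value is reported for any of these genes.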

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

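No expression result was computed, so the alternatives planned before the data were examined were not run: another count test, other normalizations and count filters, other thresholds, fits of fewer groups, leaving out single libraries, and other tests of the gene lists. No paired analysis was possible because no column of the count table was matched to a sample, and so to a replicate number. The settings below were chosen after seeing the data. Comparing whole column names with titles and descriptions matched 0 of the 12 columns. Comparing pieces of at least 4 characters with any label also matched 0. Shorter pieces, which can include run numbers, were not compared by themselves. Of the 57773 gene IDs, 52338 were found in GENCODE release 29 and 51996 in a newer table of gene names.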

Other observations

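The gene symbols of the table differ in part from current ones. Of the 52338 rows whose ID was found in GENCODE release 29, 29783 carried the same symbol as that release. None of the 36 replication-dependent histone genes, listed by their current symbols, had a row under those symbols. In the list of oxidative phosphorylation genes, 27 of 35 symbols had a row. Those without one were NDUFB8, SDHD, ATP5F1A, ATP5F1B, ATP5F1C, ATP5PB, ATP5MC1 and ATP5PO. In the list of A549 markers, 40 of 42 symbols had a row, and those without one were CCN1 and CCN2. These counts are of symbols only. Rows under older or other symbols were not searched for, and list members were not looked up by gene ID. A missing symbol therefore does not show whether the gene has another symbol in the table or no row at all.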
